A study of Mus musculus with 16 samples.

How the data were processed

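CD4 T cells were taken from mouse spleen by immunomagnetic negative selection, in which other cells are bound by beads and removed, and RNA was extracted with a Macherey-Nagel kit, per the labels' protocols. Libraries were prepared from 100 ng of RNA with a NuGEN mouse RNA-seq kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 1.8.1, HTSeq 0.6.1 and the genome build mm10. The aligner, the gene annotation, the read layout and the strand setting of the counting were not given in the sources used here. Reads from overlapping or antisense genes, and from close paralogs, therefore cannot be assigned with certainty.

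The deposited table held whole-number read counts per gene, not normalized, for 23479 genes and 16 libraries. Its columns were matched to samples by the short code that the labels give as each sample's description. The table closed with 5 lines that name no gene, and these stayed out of library sizes and tests. The line for reads outside gene models held 47.06% to 69.78% of a library's total over all lines. Reads placed at more than 1 position held 6.67% to 10.13%, and 2 of the 5 lines were at 0 throughout. The gene rows held no mitochondrially encoded genes and no immunoglobulin segments, so the lists for these were not tested. No 2 columns were identical, and pairwise Pearson correlations of log2(CPM + 1) across genes lay between 0.939 and 0.995.

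Groups came from the labels: 5 libraries from mice without tumours, 7 from day 7 and 4 from day 14 after transplant. Each library was taken as 1 mouse, since the design text counts mice. Replicate numbers come from the sample titles. The groups hold different mice, so the numbers were not used in the main model.

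Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM scaling, filterByExpr by group, a quasi-likelihood fit over all 16 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter kept 18430 genes and removed 5049. The common biological coefficient of variation was 54.5%. Standard errors of log2 changes were computed as the absolute log2 change divided by the square root of the test's F value. CPM values were scaled by TMM, except in the pairwise correlations and for the olfactory and vomeronasal receptor genes and the background, which used library totals alone. The background was set beside rises in TMM-scaled CPM without rescaling. Gene lists, 49 in all, were written before the data were examined, and 45 had at least 3 tested members. They were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Of 630 list genes, 604 were found in the table, 5 of them by an older symbol. A list index is the mean log2(CPM + 1) of the list's tested members in a library. Gene positions are those of GENCODE's annotation of GRCm38, the assembly that mm10 names, matched by symbol for 98.5% of the table's genes. Single library measures were compared with exact 2-sided permutation tests and adjusted over a family of 12. Figures and tables were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.

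Genes were named by a rule fixed before the data were examined. Per comparison, part a took the 6 highest and 6 lowest log2 changes among called genes with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. Part b took the 6 highest among those with at least 10 CPM in the lower group as well. Predicted genes, clone names and receptor segments were passed over in these parts. Part c took up to 3 called members of each list, or the most abundant member where none was called. Part d was a fixed panel of 28 genes, such as Cd4, Foxp3, Pdcd1, Mki67 and Fth1. Genes that the rule named for no comparison are marked as chosen after their values were seen. Genes that it named for another comparison, such as Bcl2, Cd74 and Zc3hav1l, also appear without this mark.

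The test was tried on simulated counts drawn from the real means and library sizes, with 200 changed genes. The changed genes were drawn only from genes at or above a minimum mean CPM, so recovery of the least abundant genes was not measured. For day 7 against control, on 17255 genes, 63% of 2-fold and 88% of 4-fold changes were recovered, with 4 false calls. For day 14 against control, on 17172 genes, the shares were 51% and 80%, with 3 false calls. For day 14 against day 7, on 17200 genes, they were 54% and 77%, with 3 false calls. No simulated change was called in the wrong direction. These shares are recovery rates at the depth of these libraries, 14493764 to 27340070 gene counts each. The simulated libraries varied independently, without differences that many genes share, so the shares and the false calls may not hold for the real libraries.

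Alternatives listed before the data were examined were other scalings (RLE and library totals), other expression filters, limma-voom, DESeq2 1.42.0, fits to the 2 compared groups alone, the replicate number as a block, a B cell index as a covariate, and each library left out in turn. Alternatives added after the data were examined were covariates for Y-linked transcripts and for the share of reads outside gene models, subsets of libraries, a filter at a mean of 5 CPM, and robust moderation. Background from genomic DNA was estimated from 1445 olfactory and vomeronasal receptor genes with a known exon length, as CPM per kilobase. Leaving out immunoglobulin genes, also listed before the data were examined, was not run because the table held none.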

Results

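Gene expression was measured by RNA sequencing in CD4 T cells from the spleens of C57BL/6 mice. Mice had received a transplant of Eµ-Myc lymphoma cells, a mouse B cell lymphoma driven by the Myc oncogene under an immunoglobulin heavy chain enhancer. Spleens were taken on day 7 (7 libraries) or day 14 (4 libraries) after transplant, and 5 libraries came from mice without tumours. The comparisons follow the study's stated subject, how CD4 T cell transcription differs in mice that carry a B cell lymphoma. Gene counts per library were 24548914 ± 2544462 in controls (SD, n = 5), 21534837 ± 3741219 at day 7 (n = 7) and 15909845 ± 1205838 at day 14 (n = 4). The share of reads outside gene models was 51.1 ± 3.65% in controls and 58.9 ± 5.28% at day 7 (exact permutation p = 0.0189, adjusted p = 0.0454). Reads placed at more than 1 position made up 9.44 ± 0.591% in controls, 7.42 ± 0.368% at day 7 and 7.42 ± 0.615% at day 14 (exact permutation adjusted p = 0.0151 and 0.0318 against control), and every library from a mouse with lymphoma, at most 7.94%, lay below every control, at least 8.74%.

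The libraries carried the transcripts of CD4 T cells. In controls Cd3e, a chain of the T cell receptor complex, stood at 1386 ± 291 CPM and Cd4 at 1261 ± 329 CPM (SD, n = 5), while Cd8a stood at 1.35 ± 0.957 CPM. Cd8b1, the other CD8 chain, was more abundant than Cd8a, and the list index of these 2 genes was 2.11 to 2.76 in controls. None of Cd4, Cd3e and Cd8a passed against control at either time, with edgeR adjusted p-values from 0.183 to 0.884. Myc, the gene that drives the transplanted lymphoma, stood at 167 ± 22.5 CPM in controls, 161 ± 33.8 CPM at day 7 and 192 ± 55.1 CPM at day 14, with adjusted p-values of 0.888 and 0.525 against control. Transcripts from the Y chromosome were abundant in control libraries 1 and 2, day 7 libraries 6 and 7 and day 14 library 4, and Xist, the female-specific transcript of the inactive X chromosome, in the others except day 14 library 1, where Xist had 162 reads and Y-linked transcripts were not abundant. Control libraries 1 and 2 also stood apart in transcripts of neutrophils and of dividing cells. S100a8, a neutrophil calcium-binding protein, reached 117 and 549 CPM in them against at most 7.57 CPM in the other control libraries, and Mki67, a marker of dividing cells, reached 1380 and 3252 CPM against at most 357 CPM.

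Day 7 against control asked what changed early after transplant. Of 18430 genes tested, 2 passed and both were higher at day 7. Zc3hav1l, a gene of a zinc finger antiviral protein family, rose from 8.82 ± 1.45 to 18.6 ± 3.17 CPM (SD, n = 5 and 7), a log2 change of 1.07 ± 0.16 (SE) with an edgeR adjusted p of 0.0219. It lies on chromosome 6 from 38287396 to 38299259 (GRCm38). The predicted gene 1810019D21Rik, named here after its values were seen because it completes the count, rose from 1.77 ± 0.871 to 7.45 ± 1.81 CPM, a log2 change of 2.07 ± 0.31 (SE) with an adjusted p of 0.0219. For both genes every day 7 library lay above every control library. No gene passed as lower with edgeR, where 2337 genes had negative and 1553 positive changes at an unadjusted p below 0.05. Both calls were lost when control library 1 or 2 or day 7 library 1, 2, 3, 5 or 7 was left out, while leaving out control library 5 gave 429 genes higher and 1026 lower. DESeq2 gave 499 and 1104, and a covariate for Y-linked transcripts, added after the data were seen, 218 and 570.

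No gene of the T cell state lists was called on its own over all genes at day 7. Foxp3, the transcription factor of regulatory T cells, stood at 219 ± 27.1 CPM against 196 ± 33.2 CPM in controls (log2 change 0.16 ± 0.16, adjusted p = 0.635). Pdcd1, which encodes the inhibitory receptor PD-1, stood at 9.48 ± 4.61 against 7.69 ± 4.29 CPM (adjusted p = 0.665). Close to the threshold were Slamf6, a receptor of lymphocyte contacts, at 155 ± 13.1 against 106 ± 24.3 CPM (adjusted p = 0.074) and Nlrc5, a regulator of MHC class I genes, at 413 ± 29.4 against 302 ± 52.1 CPM (adjusted p = 0.0709). All 16 members of the T cell receptor signalling list had positive log2 changes with a median of 0.22, and camera placed the list higher (adjusted p = 0.000586, and 0.444 with an estimated correlation). Without control libraries 1 and 2, a setting added after the data were seen, its mean was 0.023 and the direction of the test turned to lower, without a call (camera adjusted p = 0.7). The 16 memory and age-associated genes were lower as a list, with 15 negative changes, a median of -0.65 and 8 that passed adjusted over the list alone (camera adjusted p = 6.72e-08, and 0.233 with an estimated correlation). Their index was 6.28 and 6.74 in control libraries 1 and 2 against 5.33 to 5.60 in the other controls and 4.67 to 5.46 at day 7. The cytotoxic effector list (camera adjusted p = 0.0175, and 0.233 with an estimated correlation) and the senescence and secretory list (0.0331, and 0.433 with an estimated correlation) were also lower. The senescence and secretory index was 2.465 and 2.795 in control libraries 1 and 2, 1.45 to 1.85 in the other controls and 1.40 to 1.82 at day 7. The 14 naive and central memory genes (camera adjusted p = 0.507), the 20 type I interferon response genes (0.283) and the 18 interferon gamma response genes (0.355) did not pass as lists.

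Most of the lists that camera called at day 7 were lower, 24 of 26, and none of their members passed on its own over all genes. The 19 mitosis genes had a median log2 change of -1.76 (camera adjusted p = 3.41e-11, and 0.235 with an estimated correlation). Adjusted over the list alone, all 19 passed. Their example Mki67 stood at 251 ± 128 CPM at day 7 against 1088 ± 1303 CPM in controls (edgeR adjusted p = 0.0777). The 20 DNA replication genes had a median of -1.03 (camera adjusted p = 2.04e-10, and 0.235 with an estimated correlation), and 17 passed adjusted over the list alone. The 13 neutrophil genes had a median of -5.35, and Mpo, the neutrophil enzyme myeloperoxidase, stood at 5.46 ± 6.47 against 215 ± 287 CPM. Camera gave the neutrophil list an adjusted p of 1.23e-09, and 0.233 with an estimated correlation. The 10 MHC class II genes, which antigen-presenting cells such as B cells express, had a median of -1.98 (camera adjusted p = 3.87e-08, and 0.233 with an estimated correlation), and Cd74 stood at 37.4 ± 31 against 196 ± 131 CPM. The proteasome list had a median of -0.31 and the oxidative phosphorylation list one of -0.31 (camera adjusted p = 2.86e-10 and 1.35e-08, and 0.233 and 0.235 with an estimated correlation). The neutrophil, mitosis and DNA replication lists moved with control libraries 1 and 2, where the DNA replication index was 5.55 and 6.46 against at most 4.53 in the other controls, and without these 2 libraries no gene was higher and the mean log2 change of the mitosis list went from -1.71 to -0.09. For the proteasome, control libraries 3 to 5 also lay above all 7 day 7 libraries, with an index of at least 6.02 against at most 5.95.

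**Figure D1:**
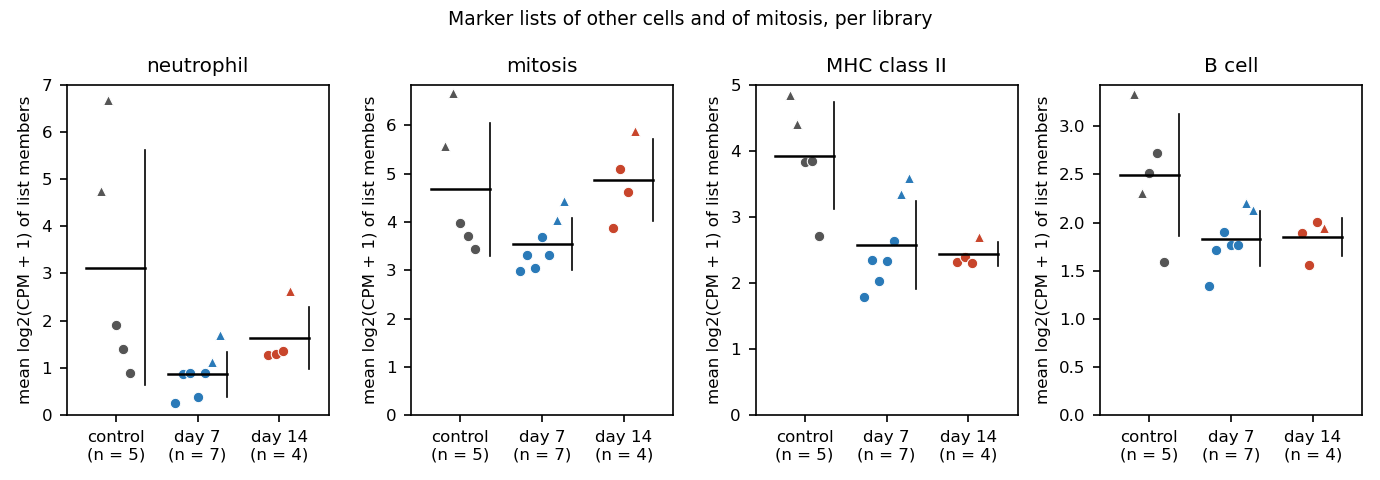
List index per library (mean log2 of CPM + 1 over a list's members) for the neutrophil, mitosis, MHC class II and B cell lists in control, day 7 and day 14 libraries. Points are libraries, triangles are libraries with Y-linked transcripts, bars are means and vertical lines SDs. Control libraries 1 and 2 reached a neutrophil index of 4.75 and 6.68 against at most 1.91 in the other controls, and day 14 library 4 reached 2.62.

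Day 14 against control asked what had changed at the later time. Here 246 genes were higher and 331 lower among 18430. Genes of regulatory and follicular helper T cells were among the higher ones. Foxp3 rose from 196 ± 33.2 to 370.3 ± 139 CPM (SD, n = 5 and 4), a log2 change of 0.92 ± 0.19 (SE) with an edgeR adjusted p of 0.0194. Cxcr5, the chemokine receptor that brings T cells to B cell follicles, rose from 20.4 ± 6.3 to 58.9 ± 18.5 CPM (log2 change 1.53 ± 0.31, adjusted p = 0.0187). Pdcd1 rose from 7.69 ± 4.29 to 27.5 ± 7.54 CPM (log2 change 1.84 ± 0.39, adjusted p = 0.0233). Genes of naive cells, cholesterol synthesis, iron storage and the immediate early response were among the lower ones, such as Ccr7, the lymph node homing receptor, which fell from 427 ± 163 to 212 ± 49.5 CPM (log2 change -1.01 ± 0.25, adjusted p = 0.0418).

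Every one of the 14 regulatory T cell genes had a positive log2 change at day 14, with a median of 0.62. Over all genes 4 of them rose, and 8 adjusted over the list alone. Besides Foxp3 these were Ikzf2, which encodes the transcription factor Helios (112 ± 16.2 to 212 ± 54.3 CPM, adjusted p = 0.0248), Klrg1 (2.13 ± 0.609 to 7.26 ± 2.49 CPM, adjusted p = 0.0424) and Itgae, an integrin chain that falls outside the naming rule and was chosen after its value was seen (4.32 ± 2.42 to 10.6 ± 2.96 CPM, adjusted p = 0.0435). Camera called the list higher (adjusted p = 7.94e-06, and 0.188 with an estimated correlation). The 14 follicular helper genes likewise all had positive changes, with a median of 1.15. Over all genes 5 of them rose, and 8 adjusted over the list alone. They were Cxcr5, Pdcd1, Slamf6 (106 ± 24.3 to 203 ± 28.3 CPM, adjusted p = 0.00535), the transcription factor Maf (68.3 ± 8.84 to 169 ± 59 CPM, adjusted p = 0.00817) and the TNF family ligand Tnfsf8 (23.8 ± 3.4 to 47.6 ± 11.4 CPM, adjusted p = 0.0176). Camera gave an adjusted p of 3.14e-07, and 0.291 with an estimated correlation. Bcl6, the transcription factor that defines follicular helper cells, did not pass (edgeR adjusted p = 0.754), and was chosen after its value was seen.

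**Figure D2:**
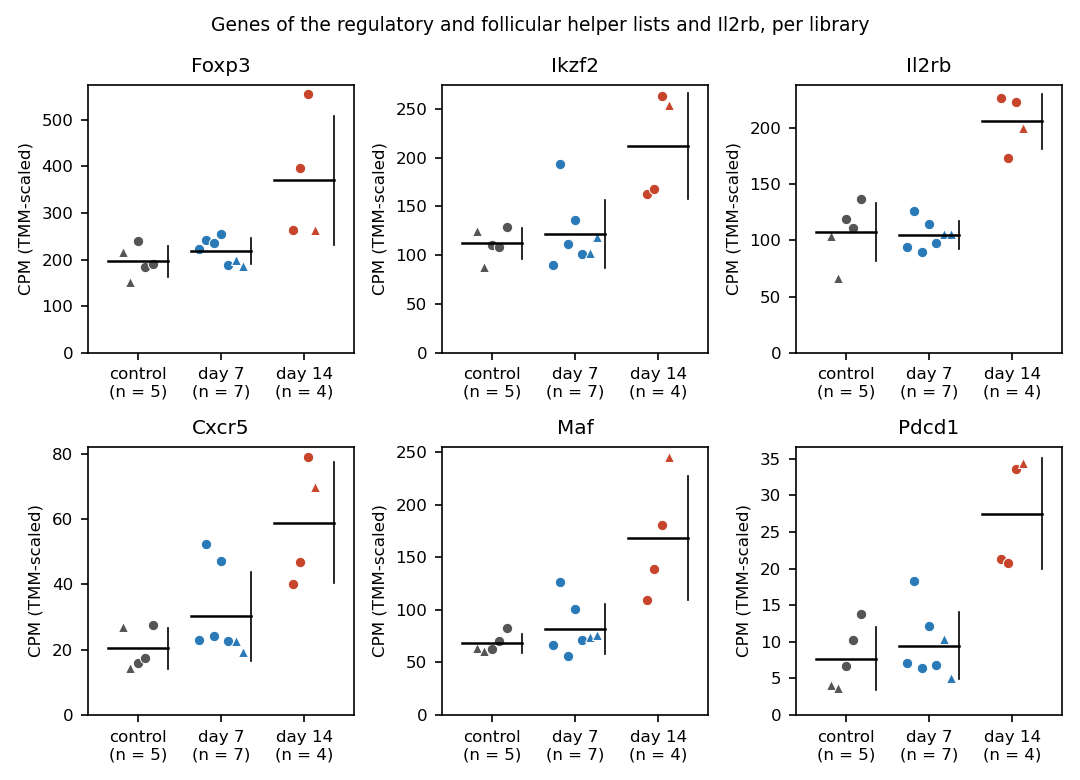
TMM-scaled CPM per library of Foxp3, Ikzf2, Il2rb, Cxcr5, Maf and Pdcd1 in control, day 7 and day 14 libraries. Points are libraries, triangles are libraries with Y-linked transcripts, bars are means and vertical lines SDs. Each of the 4 day 14 libraries lay above all 5 controls for each gene, as for Il2rb at 206 ± 24.7 against 107.5 ± 25.8 CPM.

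Other receptors of T cell activation rose in part at day 14. Of 14 activation genes, 2 rose: Tnfrsf4, which encodes the costimulatory receptor OX40 (45.4 ± 14 to 95.1 ± 13 CPM, log2 change 1.07 ± 0.17, adjusted p = 0.00812), and Il2rb, a chain of the interleukin 2 and interleukin 15 receptors (log2 change 0.94 ± 0.16, adjusted p = 0.00812). The list did not pass (camera adjusted p = 0.251). Of 12 Th1 genes, 2 rose, the chemokine receptor Cxcr3 (12.9 ± 4.85 to 30.8 ± 9.55 CPM, adjusted p = 0.0275) and the interleukin 12 receptor chain Il12rb1 (8.26 ± 2.53 to 18 ± 2.24 CPM, adjusted p = 0.0207). The list did not pass (camera adjusted p = 0.0904), and neither Tbx21 (adjusted p = 0.426) nor Ifng (0.821) did. Among 15 inhibitory receptor and exhaustion genes, Pdcd1 rose and 4632428N05Rik, an older symbol of Vsir, fell (396 ± 50 to 288 ± 49.5 CPM, adjusted p = 0.0463). Lag3 stood at 28.6 ± 17.2 against 8.93 ± 5.06 CPM (adjusted p = 0.068) and Ctla4 at 141 ± 32.1 against 104 ± 64.2 CPM (adjusted p = 0.581). Among 13 cytotoxic effector genes Klrg1 and Cst7 rose while Klrd1 and Fasl (named after its value was seen) fell, and the list did not pass (camera adjusted p = 0.231). Nt5e, which encodes the ectonucleotidase CD73, rose from 34.3 ± 8.53 to 79.5 ± 16.6 CPM (adjusted p = 0.0102).

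Several lists of growth and metabolism were lower at day 14, while mitosis (camera adjusted p = 0.753) and glycolysis (0.297) did not pass. Without control libraries 1 and 2 the mitosis list turned to higher, with a mean log2 change of 1.42 (camera adjusted p = 1.02e-06). All 16 cholesterol synthesis genes had negative log2 changes with a median of -0.59, 3 fell over all genes and 12 adjusted over the list alone (camera adjusted p = 7.26e-10, and 0.291 with an estimated correlation). Among them were the sterol demethylase Cyp51 (50.6 ± 4.99 to 26.6 ± 9.19 CPM, adjusted p = 0.0182) and the squalene synthase Fdft1 (20.7 ± 3.05 to 13.7 ± 1.4 CPM, adjusted p = 0.0459). All 20 ribosomal protein genes and all 21 nuclear-encoded oxidative phosphorylation genes had negative changes, with medians of -0.38 and -0.39, and 1 gene of each fell over all genes, Rplp0 and Ndufa2. Camera gave adjusted p-values of 2.09e-11 and 6.56e-10, both 0.291 with an estimated correlation. Day 14 library 2, with 54.4% of reads outside gene models, had indices of 9.42 and 5.96, within the control ranges, while libraries 1, 3 and 4, with 69.8%, 66.3% and 62.3%, had 8.97, 8.88 and 8.97 for ribosomal proteins and 5.32, 5.52 and 5.79 for oxidative phosphorylation. The cholesterol synthesis index was likewise 4.80 in library 2, within the control range of 4.77 to 5.12. It was 4.09, 4.08 and 4.49 in libraries 1, 3 and 4. Of 15 iron handling genes, 2 fell, the ferritin heavy chain Fth1 (701 ± 195 to 354 ± 115 CPM, adjusted p = 0.0211) and Pcbp1 (189.5 ± 15.6 to 135 ± 30.3 CPM, adjusted p = 0.0485), with camera at 0.00106 and 0.291 with an estimated correlation. The iron handling index was 5.78 and 6.02 in control libraries 1 and 2, 5.25 to 5.36 in the other controls and 5.02 to 5.47 at day 14. Of 16 immediate early genes, 15 had negative changes with a median of -0.72 and 3 fell, Ier2, Btg2 and Atf3 (camera adjusted p = 1.31e-07, and 0.291 with an estimated correlation). Ier2 fell from 94.9 ± 3.3 to 55.4 ± 9.53 CPM. Of 14 naive and central memory genes, Ccr7 and Dapl1 fell and the survival gene Bcl2 rose (342 ± 79.3 to 554 ± 158 CPM, adjusted p = 0.04998), with a list median of -0.42 and camera at 0.000841, and 0.424 with an estimated correlation. The ferroptosis regulator Gpx4 (adjusted p = 0.168), the transferrin receptor Tfrc (0.389) and the inhibitory receptor ligand Cd274 (0.944) did not pass.

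**Figure D3:**
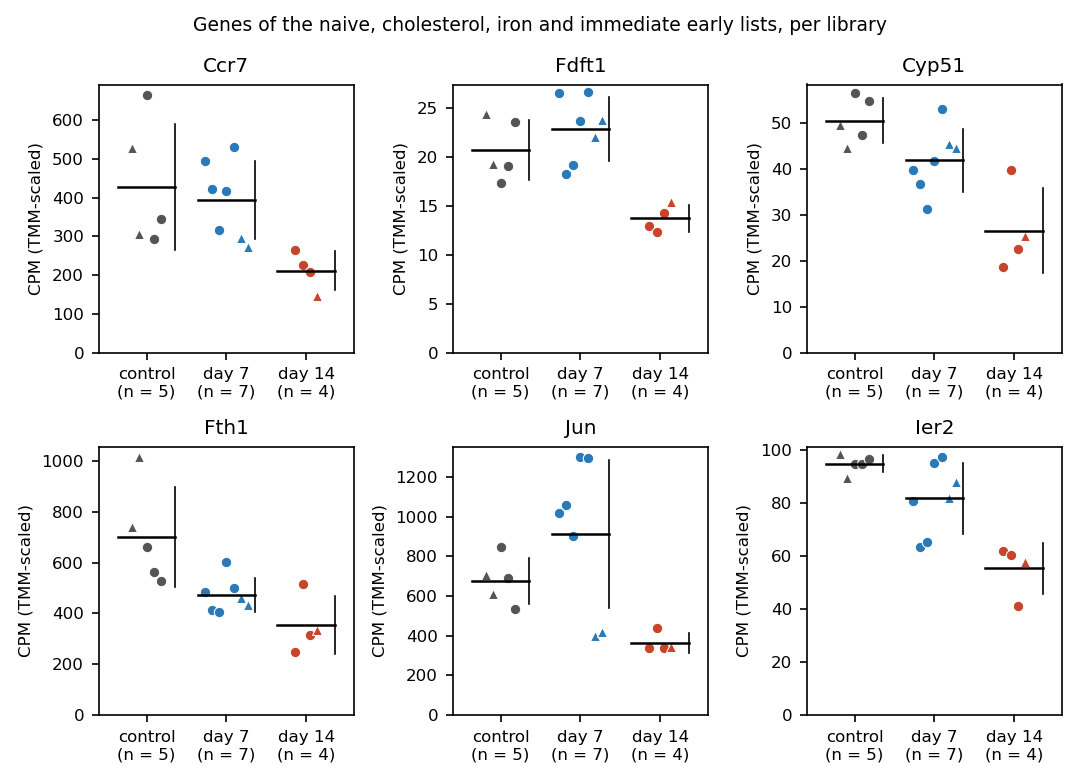
TMM-scaled CPM per library of Ccr7, Fdft1, Cyp51, Fth1, Jun and Ier2 in control, day 7 and day 14 libraries. Points are libraries, triangles are libraries with Y-linked transcripts, bars are means and vertical lines SDs. Day 14 means lay below control means for each gene, and Jun in day 7 libraries spanned 397 to 1302 CPM.

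Of the lists of other cells, those of MHC class II, B cells and neutrophils were lower at day 14, while the macrophage and monocyte (camera adjusted p = 0.208), dendritic cell (0.112) and basophil and mast cell lists (0.304) did not pass. H2-Aa, H2-Ab1 and H2-Eb1, which encode MHC class II chains, fell from 16.6 ± 11.3, 39.8 ± 26.8 and 20.1 ± 11.9 CPM to 0.917 ± 0.132, 2.42 ± 1.71 and 1.29 ± 0.818 CPM (adjusted p = 0.0323, 0.0438 and 0.0295). With Cd74 they made 4 of 10 list members that fell (list median -1.50, camera adjusted p = 3.37e-06, and 0.291 with an estimated correlation). The B cell receptor component Cd79a fell from 9.08 ± 4.45 to 2.64 ± 1.15 CPM (adjusted p = 0.0275), and the B cell list had a median of -1.13 (camera adjusted p = 0.000841, and 0.419 with an estimated correlation). The B cell groups overlapped, with an index of 1.90, 1.56, 2.01 and 1.94 in day 14 libraries 1 to 4. It was 1.59 in control library 5 and 2.31 to 3.33 in the other controls. Of 13 neutrophil genes, 3 fell, S100a8, S100a9 and Ngp, with a list median of -4.64 (camera adjusted p = 0.00206, and 0.531 with an estimated correlation). Their control means rested on control libraries 1 and 2, without which the list did not pass, and day 14 library 4 alone held 1226 CPM of Mpo against at most 36.1 CPM in the other day 14 libraries.

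The largest changes at day 14 under the naming rule included 2 muscle genes. Neb, the muscle protein nebulin (chromosome 2, 52136647 to 52378474, GRCm38), rose from 44.2 ± 5.79 to 380.5 ± 149 CPM (log2 change 3.10 ± 0.24, adjusted p = 1.98e-06). Ttn, the muscle protein titin (chromosome 2, 76703980 to 76982547), rose from 101 ± 14.9 to 514 ± 134 CPM (log2 change 2.35 ± 0.29, adjusted p = 0.00174). Nrbp2, Ston1, Cdh23 and Unc13a rose by log2 changes of 1.92 to 2.41 from levels of 2.36 to 7.37 CPM. Ptpn13, Podnl1 and Dst rose by 1.33 to 1.44. Besides the MHC class II genes, Plbd1 (log2 change -4.38 ± 1.09, adjusted p = 0.0415), Faim3, an older symbol of the IgM receptor gene Fcmr (-2.49 ± 0.45, adjusted p = 0.0102), and the cell cycle regulator Rgcc (-1.47 ± 0.29, adjusted p = 0.0175) were lowest.

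The day 14 counts depended on the fit. With only the 2 groups fitted 4 genes were higher and 0 lower, with the share of reads outside gene models as a covariate (added after the data were seen) 1 was higher, Neb, and 0 lower, and with library totals as the only scaling 699 were higher and 100 lower. That share differed between groups, at 51.1 ± 3.65% in controls and 63.2 ± 6.6% at day 14 (exact permutation p = 0.0238, adjusted p = 0.0476, smallest possible 0.00794), and library totals moved the median log2 change of all genes from 0.12 to 0.32.

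**Figure D4:**
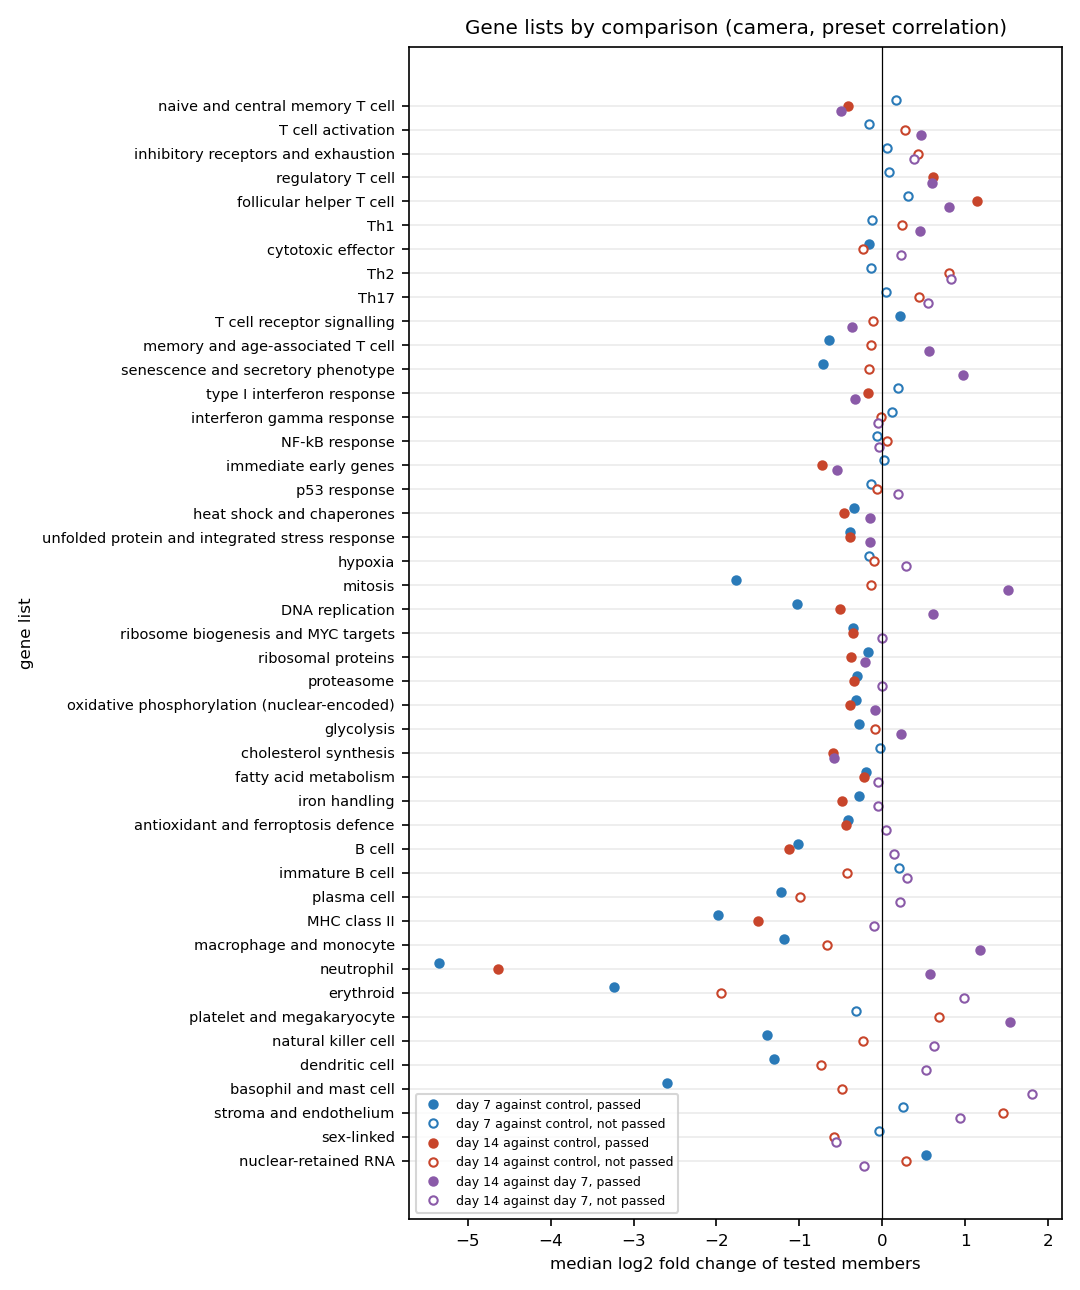
Median log2 change of each gene list at day 7 against control, day 14 against control and day 14 against day 7. Each point is a list, and filled points passed camera with the preset correlation, 26, 19 and 21 lists in the 3 comparisons. The neutrophil list has the lowest median against control at both times, -5.35 and -4.64.

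Day 14 against day 7 asked what differed between the 2 times in mice with lymphoma, and is also the test of whether changes from control differed. Here 76 genes were higher and 102 lower at day 14. The regulatory T cell list was higher again, with all 14 changes positive and a median of 0.60, and its call held with an estimated correlation (camera adjusted p = 5.13e-09, and 0.0235 with an estimated correlation). Over all genes 4 of its members rose, and 10 adjusted over the list alone. Foxp3 rose from 219 ± 27.1 to 370.3 ± 139 CPM (log2 change 0.76 ± 0.17, edgeR adjusted p = 0.0419), Klrg1 from 1.92 ± 1.08 to 7.26 ± 2.49 CPM (adjusted p = 0.0317), and Tnfrsf18, which encodes the receptor GITR, from 41.7 ± 4.37 to 65.3 ± 10.2 CPM (adjusted p = 0.0394). Of 14 activation genes 4 rose and 1 fell (list median 0.47, camera adjusted p = 0.00201, and 0.441 with an estimated correlation). Tnfrsf4 rose from 40.1 ± 4.95 to 95.1 ± 13 CPM (log2 change 1.25 ± 0.16, adjusted p = 0.00126), while Cd40lg, the helper T cell ligand of CD40, fell from 282 ± 76.9 to 123 ± 39.9 CPM (log2 change -1.19 ± 0.25, adjusted p = 0.0291). Of 14 follicular helper genes Maf and Pdcd1 rose (list median 0.81, camera adjusted p = 7.69e-07, and 0.441 with an estimated correlation). The groups overlapped, with a follicular helper index of 4.55, 4.46, 5.14 and 5.34 in day 14 libraries 1 to 4 against 3.69 to 4.89 at day 7.

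By camera with the preset correlation, the naive cell, signalling and immediate early lists were lower at day 14 than at day 7. Of 14 naive and central memory genes 3 fell, Foxp1 (1084 ± 103 to 696 ± 50.8 CPM, adjusted p = 0.0221), Foxo1 (699 ± 83.3 to 420 ± 90.5 CPM, adjusted p = 0.033) and Dapl1, and Bcl2 rose. The list median was -0.50 (camera adjusted p = 7.69e-07, and 0.441 with an estimated correlation). All 16 T cell receptor signalling genes had negative changes with a median of -0.36, none passed over all genes and 7 passed adjusted over the list alone (camera adjusted p = 1.38e-07, and 0.441 with an estimated correlation). Of 16 immediate early genes 2 fell, Ier2 and Jun (list median -0.54, camera adjusted p = 1.38e-07, and 0.432 with an estimated correlation). Jun fell from 912 ± 375 to 363 ± 49.4 CPM (log2 change -1.33 ± 0.28, adjusted p = 0.0318), and the day 7 libraries with Y-linked transcripts stood at 397 and 417 CPM, within the day 14 range of 335 to 437 CPM. All 16 cholesterol synthesis genes had negative changes with a median of -0.58 (camera adjusted p = 2.41e-11, and 0.36 with an estimated correlation), and Fdft1 fell from 22.8 ± 3.26 to 13.7 ± 1.4 CPM (adjusted p = 0.0248). Day 14 library 2, with the smallest share of reads outside gene models at day 14, had a cholesterol synthesis index of 4.80. That lay within the day 7 range of 4.61 to 5.14, and the other day 14 libraries had 4.08 to 4.49. Irf1, a transcription factor of the interferon gamma list, fell from 293 ± 30.8 to 181 ± 49.9 CPM (log2 change -0.70 ± 0.13, adjusted p = 0.02), and 18 of 20 type I interferon response genes had negative changes (list median -0.32, camera adjusted p = 5.42e-05, and 0.515 with an estimated correlation). The type I interferon index was 5.79 in day 14 library 2, above every day 7 library, at 4.99 to 5.60. It was 4.59, 4.84 and 4.52 in day 14 libraries 1, 3 and 4. All 19 mitosis genes had positive changes with a median of 1.52. None passed over all genes and 17 adjusted over the list alone (camera adjusted p = 9.8e-11, and 0.441 with an estimated correlation), and Mki67 stood at 850.3 ± 492 against 251 ± 128 CPM (adjusted p = 0.165).

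The largest rises between the times under the naming rule were those of Podxl, a cell surface sialomucin (log2 change 3.46 ± 0.82, adjusted p = 0.0496), and Neb (3.00 ± 0.21, adjusted p = 4.26e-07). The protease inhibitor gene Serpina3g rose by 1.67 ± 0.27 and S100a6 by 1.63 ± 0.35 on the log2 scale. Socs3, a suppressor of cytokine signalling (chromosome 11, 117966079 to 117970047), rose from 71.2 ± 7.67 to 198 ± 58.4 CPM (log2 change 1.47 ± 0.17, adjusted p = 0.000348), and the glucocorticoid-induced gene Fkbp5 from 48.7 ± 6.57 to 122 ± 63.4 CPM (adjusted p = 0.0117). Cnga1, Rgcc, Lypd6b, Arhgap29, the stress-response phosphatase subunit Ppp1r15a and Rapgef4 were lowest, with log2 changes from -1.83 to -1.21. Ppp1r15a fell from 704.5 ± 225 to 299 ± 78.3 CPM (adjusted p = 0.0317). With only the 2 groups fitted 316 genes were higher and 396 lower, with library totals as the only scaling 150 and 41, and without day 14 library 3 17 and 8.

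Against control, 1 gene passed at both times in the same direction, Zc3hav1l, which was higher at day 7 and at day 14 (log2 change 0.79 ± 0.18, adjusted p = 0.0275). Independent lists of these sizes would share 0.0267 genes, and 20 simulated pairs of unchanged groups against the same controls shared a median of 0. The simulated groups had at most 1 call at either time, so they could hardly share any and do not test the overlap. With 2 genes called at day 7, the overlap could not exceed 2. When the controls were split so that each time had its own, the shared genes had a median of 0 and a range of 0 to 3 over 20 splits. These splits fitted only the 2 compared groups, with fewer controls. With all controls that fit called 4 genes at each time, so little could be shared and the splits do not test the overlap either. DESeq2 gave 346 shared genes with all controls.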

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

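In 561 groups of library values, a gap test marked single libraries that lay apart from their own group, and chance alone marks about 1 in 20 groups (28.1 here). It marked 35 values, 30 high and 5 low, of which 8 lay in control library 2, 7 in day 14 library 4 and 5 in day 7 library 2. The tests of sex, of the share of reads outside gene models and of the control libraries, and the spread of the background rise, in this part were chosen only after the results were seen.

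In control library 2 the values were S100a8 at 549.1 CPM, S100a9 at 396.1 CPM, Ngp at 148.5 CPM, Sdha at 277.8 CPM, Cd3e at 880.4 CPM (low), olfactory and vomeronasal receptor genes at 209.3 CPM, and list indices of 9.232 for ribosomal proteins (low) and 6.325 for the proteasome. In the other controls they were Cd8a at 3.03 CPM in library 1, a type I interferon index of 5.745 in library 4, and Cdkn2a at 0.3 CPM and Pkm at 475.2 CPM in library 5. Day 14 library 4 held Mpo at 1226 CPM, Elane at 146.3 CPM, Flt3 at 25.76 CPM and Cdkn1a at 7.07 CPM, and indices of 4.374 for immature B cells, 2.618 for neutrophils and 2.991 for basophils and mast cells. Day 14 library 2 held Jun at 437.1 CPM and Neb at 160.2 CPM (low). Day 7 library 2 held Dst at 150.5 CPM, Osbpl3 at 21.66 CPM, Ptpn13 at 72.09 CPM, Socs3 at 87.21 CPM and Stat4 at 208.6 CPM. In the other day 7 libraries the values were a Th2 index of 1.945 and Ctsw at 26.3 CPM (both low, library 1), olfactory and vomeronasal receptor genes at 504.5 CPM, Pkm at 487.5 CPM and Zc3hav1l at 25.3 CPM (library 3), Hsp90ab1 at 2210 CPM (library 4), Cd8a at 1.4 CPM (library 5), and S100a9 at 5.64 CPM and Tfrc at 61.37 CPM (library 7). The mean share of reads outside gene models was 58.95% at day 7 and 63.19% at day 14, above the control range of 47.06% to 56.67%. The change from control differed between day 14 and day 7 for 178 genes and 21 gene lists, of which 1, the regulatory list, passed with an estimated correlation (adjusted p = 0.0235).

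The neutrophil, mitosis and MHC class II lists were lower at day 7 than in controls, with adjusted p of 0.233, 0.235 and 0.233 with an estimated correlation. Without control libraries 1 and 2, 17.6% of the neutrophil change (mean log2 change -5.05 to -0.89, over members tested in both fits) and 5.4% of the mitosis change (-1.71 to -0.09) remained, so these 2 libraries may account for both, although they were picked for such transcripts and the test is close to circular. For MHC class II 59.9% remained (-1.61 to -0.97), so the reading stayed open. Among libraries with Y-linked transcripts, only 2 per group, the controls were the same libraries 1 and 2, so a gap was partly built in. For neutrophils the lowest of these controls lay above the highest day 7 library by 3.06 index units. That gap was more than the summed ranges of these libraries, 2.50, which argued against sex of the animals alone among these few libraries. With Y-linked transcripts as a covariate 70.8% of the neutrophil change remained, so a part for sex stayed open. With Y-linked transcripts as a covariate 97% of the MHC class II change remained, which argued against sex alone there too, while for mitosis 64.5% remained and the gap of 1.12 was smaller than the summed ranges, so sex stayed open.

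The genes called at day 14 against control could be affected by the larger share of reads outside gene models. With that share as a covariate a median of 73.5% of the log2 change remained (quartiles 60.3% and 90.2%), and with a median SE that went from 0.17 to 0.23 the share could not be told apart from the time after transplant. Reads from genomic DNA were excluded for genes of at least 10 CPM, where background accounted for most of the rise in 0% of the genes, and for the lower genes, where it would give a log2 change of -0.00698 against a median of -0.61. For genes under 10 CPM it accounted for most of the rise in 4.81% of 104 genes, under the bound of 20% set in advance for excluding it, but in 20.2% at the upper end of the background rise (the upper limit of its normal confidence interval, added after the result was seen), so genomic DNA stayed open there, although no value reached 50%.

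The regulatory and follicular helper lists were higher at day 14 than in controls, with adjusted p of 0.188 and 0.291 with an estimated correlation. Background from genomic DNA made up 0.732% and 0.811% of their summed rise in CPM, which excluded it. With Y-linked transcripts as a covariate 102% and 106% of the mean log2 changes remained, which argued against sex of the animals alone. With the share of reads outside gene models 92.7% (0.73 to 0.68) and 79.8% (1.09 to 0.87) remained. These percentages carry no error, and the share moved with the time after transplant, so this fit cannot exclude the share as a cause. A possible reading, offered only as a hypothesis, is that regulatory and follicular helper cells made up a larger part of the CD4 fraction by day 14. It was not tested, since counts from whole populations do not separate cell numbers from expression per cell, and flow cytometry of Foxp3 and Cxcr5 at both times would test it.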

How the results depend on the processing

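The gene counts depended on the setting, and the cause was not tested for any count that did not hold. Settings with covariates for Y-linked transcripts or for the share of reads outside gene models, those without control libraries 1 and 2, those with Xist-bearing libraries only, and the filter at 5 CPM were chosen only after the results were seen. Splits of the libraries were drawn, 100 per comparison with the real groups among them. For day 7 against control 3 of them gave at least the real number of calls (2). The number was 4 for day 14 against control (577) and 1, the real groups alone, for day 14 against day 7 (178). Each share lay under the bound of 0.05 set in advance. Against control, other splits gave more calls than the real groups at both times, so chance was not excluded there. For day 14 against day 7 no other split drawn reached the real count, which argued against chance alone. The highest other splits gave 478, 770 and 17 calls. The first 2 of these, above the real counts, point to structure among the libraries beyond the groups. The analysis without immunoglobulin genes was not run because the table held none.

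With the replicate number as a block, day 7 against control gave 6 higher and 29 lower genes, day 14 against control 25 and 21, and day 14 against day 7 9 and 19. The numbers tie no mice together by the labels, and 13 pairs of libraries with the same number in 2 groups had a median correlation of -0.075, with 1 of 14 libraries closest to its own number.

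For day 7 against control, 0 genes were higher with the B cell index, with the share of reads outside gene models, with that share and Y-linked transcripts coded to include day 14 library 1, and without control libraries 1 and 2. Y-linked transcripts as a covariate gave 218 higher and 570 lower, and 93 and 203 with day 14 library 1 coded among them. Y-linked transcripts and the share together gave 249 and 403, libraries with Xist only 68 and 212, and a mean of at least 5 CPM 73 and 90. Fitting only the 2 groups gave 1 lower, and DESeq2 499 higher and 1104 lower. Of 26 lists, 0 remained with an estimated correlation and 5 with fry.

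For day 14 against control, library totals gave 699 higher and 100 lower, no expression filter 210 lower, limma-voom 538 higher and the B cell index 92 higher and 137 lower. The share of reads outside gene models gave 1 higher and 0 lower, Y-linked transcripts 542 lower, both together 9 and 9, and both with day 14 library 1 coded among them 4 and 1. Leaving out control libraries 1 and 2 gave 456 higher, libraries with Xist only 139 and 84, and a mean of at least 5 CPM 375 higher. Fitting only the 2 groups gave 4 higher and 0 lower, and DESeq2 852 and 699. Against 19 lists with the preset correlation, 0 passed with an estimated correlation and 8 with fry, 7 of them among the 19 and Th17 not.

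For day 14 against day 7, library totals gave 150 higher and 41 lower, and the share of reads outside gene models 39 and 46. Y-linked transcripts gave 556 and 475, and 131 and 166 with day 14 library 1 coded among them. Y-linked transcripts and the share gave 453 and 329. Leaving out control libraries 1 and 2 gave 388 and 450, libraries with Xist only 388 and 161, and a mean of at least 5 CPM 153 higher. Fitting only the 2 groups gave 316 and 396, and DESeq2 354 and 361. Against 21 lists with the preset correlation, 1 passed with an estimated correlation and 3 with fry, Th17 not being among the 21. The overlap of day 7 and day 14 calls, 1 gene, was 346 with DESeq2 and 0 with split controls.

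Directions turned in 3 gene and 25 list values, where the direction of a list is that of camera and its mean can keep its sign. At day 7 against control, the mean log2 changes were 0.05, 0.052 and 0.033 for ribosomal proteins and 0.19, 0.192 and 0.18 for cholesterol synthesis (with the share, with Y-linked transcripts and the share, and with day 14 library 1 coded among them). T cell receptor signalling stood at 0.023 and naive cells at -0.086 without control libraries 1 and 2, and T cell receptor signalling at 0.035 with Xist only. At day 14 against control the same 3 settings gave 0.067, 0.061 and 0.074 for type I interferon and 0.141, 0.152 and 0.151 for interferon gamma. T cell receptor signalling stood at 0.117 and 0.11 with the last 2. Mitosis stood at 0.438 with Y-linked transcripts, 0.443 and 0.324 with the last 2 settings, 1.422 without control libraries 1 and 2 and 1.213 with Xist only. Without these controls and with Xist only, DNA replication stood at 0.589 and 0.516 and Mki67 at 1.655 and 1.603. Erythroid genes stood at 1.38 with Xist only, and Xist itself at 1.285 with day 14 library 1 coded among the Y-linked libraries.

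With each library left out in turn, day 7 against control ranged from 0 to 429 higher and 0 to 1026 lower, day 14 against control from 42 to 487 and 18 to 999, and day 14 against day 7 from 17 to 213 and 8 to 318. The lists ranged from 24 to 29, 18 to 23 and 15 to 23. For day 7 against control the counts were 5 and 7 without control 3, 4 and 5 without control 4, 429 and 1026 without control 5, 5 and 3 without day 14 library 1, 18 and 59 without day 14 library 4, 4 and 0 without day 7 library 6, and 0 and 0 without control 1, control 2 or day 7 library 1, 2, 3, 5 or 7. For day 14 against control they were 99 and 119, 487 and 519, 64 and 18, 121 and 83, and 353 and 557 without controls 1 to 5, and 86 and 27, 459 and 999, 42 and 23, and 55 and 54 without day 14 libraries 1 to 4. Without day 7 library 1, 2, 4, 5 or 6 they were 151 and 96, 173 and 212, 165 and 209, 124 and 76, and 163 and 197. For day 14 against day 7 they were 213 and 318 without control 2, 73 and 52 without control 4, and 41 and 10, 101 and 276, 17 and 8, and 17 and 12 without day 14 libraries 1 to 4. Without day 7 library 1, 3, 4, 5, 6 or 7 they were 30 and 13, 42 and 50, 32 and 32, 27 and 14, 38 and 65, and 50 and 108.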

Other observations

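The lists described here were picked, and the rank correlation below was chosen, only after the results were seen. At day 14 against day 7 the memory and age-associated list was higher (median log2 change 0.56, 15 of 16 changes positive, camera adjusted p = 6.17e-05, and 0.45 with an estimated correlation), with 1 member called over all genes and 6 adjusted over the list alone. Its index was 5.10, 5.54, 5.65 and 6.57 in day 14 libraries 1 to 4 against 4.67 to 5.46 at day 7, and at day 14 against control the list did not pass (camera adjusted p = 0.304). The platelet and megakaryocyte list had a median of 1.55 with all 8 changes positive (camera adjusted p = 0.0158, and 0.441 with an estimated correlation). The macrophage and monocyte list had a median of 1.18 (camera adjusted p = 0.0432, and 0.644 with an estimated correlation). Elane and Mpo, enzymes of granulocyte precursors, rose at day 14 against day 7 (edgeR adjusted p = 0.0437 and 0.0439), and both means rested on day 14 library 4.

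At day 7 against control the nuclear-retained RNA list was higher, with all 5 changes positive and a median of 0.53 (camera adjusted p = 0.000884, and 0.233 with an estimated correlation), while Malat1, a long nuclear RNA, did not pass (edgeR adjusted p = 0.117). That list holds Xist, whose own change was the median, and its index was 6.23 to 7.12 in control and day 7 libraries with Y-linked transcripts (2 of 5 and 2 of 7) against 8.56 to 9.45 in the others. Without control libraries 1 and 2 it did not pass. Erythroid genes had a median of -3.24 at day 7 with all 7 changes negative (camera adjusted p = 6.28e-05, and 0.235 with an estimated correlation), and their index was 4.95 and 6.44 in control libraries 1 and 2 against 1.21 to 2.51 in the other controls and 0.566 to 3.53 at day 7. The B cell list at day 7 had a median of -1.02 with all 15 changes negative (camera adjusted p = 2.4e-05, and 0.235 with an estimated correlation). Its index was 1.345 to 2.21 at day 7, 1.59 in control library 5 and 2.31 to 3.33 in the other controls. At day 14 against control the heat shock and chaperone list had a median of -0.46 with all 17 changes negative (camera adjusted p = 1.2e-06, and 0.394 with an estimated correlation). Its index was 6.23, 7.85, 7.00 and 6.71 in day 14 libraries 1 to 4 against 6.92 to 7.92 in controls.

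Median, mean and test differed in sign for some lists. At day 7 the regulatory T cell list had a median of 0.085 and a mean of -0.008, the immediate early list 0.02 and -0.356, the immature B cell list 0.204 and -0.491, and the inhibitory receptor list 0.054 and -0.096. At day 14 against control the interferon gamma list had a median of -0.018 and a mean of 0.088. Olfactory and vomeronasal receptor genes, which are known mainly from sensory neurons, stood at 92.7 ± 66.3 CPM in controls (SD, n = 5) and 382 ± 262 CPM at day 14 (n = 4, exact permutation p = 0.0159, adjusted p = 0.0454). The first principal component held 37.2% of the variance and had a rank correlation of 0.865 with the share of reads outside gene models.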
